A study of Mus musculus with 12 samples.

How the data were processed

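RNA of lineage-depleted bone marrow from 6 E4bp4 knockout and 6 wild type mice was hybridised to GeneChip Mouse Gene 1.0 ST arrays, per the labels' protocols and the series design text. The values analysed are log2 levels per transcript cluster that the authors made with GeneSpring GX version 11 and the RMA16 algorithm, per the series design text. That text also names a filter between the 20th and 100th percentile, a moderated test and Benjamini-Hochberg correction. The deposited table holds 34760 transcript clusters, before that filter. The log2 scale was inferred from the range of the values, 3.18 to 14.33. The probe annotation behind the authors' summarisation is not given in the sources used here, and scanner files were not used here, so background correction and summarisation could not be varied. RMA forces the arrays toward a common distribution, so a shift of most genes in 1 direction would be hidden.

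Groups were taken from the genotype in the labels, and all 12 columns were matched to samples. A transcript cluster was kept when it reached its array's 20th percentile on at least 1 array, which left 29541 and removed 5219. Platform annotation named 1 gene for 21640 transcript clusters, several for 1321 and none for 11799; of those tested, 19278 had 1 gene, 1033 several and 9230 none, control probes included. Entrez identifiers of 21553 were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and neighbouring genes. No coordinates are printed because the build behind the array values is not given in the sources used here. For gene lists and windows, 17807 genes had 1 transcript cluster each, the one with the highest mean level; 852 genes had more than 1. As a guide to background, the Y-linked genes Eif2s3y, Kdm5d and Uty averaged 4.02, 4.63 and 4.49 on the 11 arrays without male signal.

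Differences, knockout minus wild type, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate) at a Benjamini-Hochberg adjusted p of 0.05. Single values were also tested by two-sided exact permutation of the 12 arrays. Before the data were examined, 29 gene lists were written, of which 28 were tested with camera (preset correlation 0.01) and with fry, and the sex-linked list served as a check; 505 of the 589 distinct list genes were tested. Named genes followed a rule also written before the data were examined: Nfil3, 14 genes of the E4bp4 field, the 10 largest changes in each direction past the threshold, and up to 4 genes of lowest p per list. Since 0 passed the threshold, the 10 of lowest p in each direction that name 1 gene were taken. Genes within 10 Mb of Nfil3 were compared with the others by Fisher's exact test.

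Alternatives written before the data were examined covered the filter, scaling, variance trend, array weights, a sex-linked covariate, the replicate number as a block, each array left out, other gene set tests and other windows. Those added after seeing the data were leaving out both arrays numbered 1, exact permutation of list means, an estimated correlation without knockout replicate 1, and unadjusted thresholds. The limma and camera steps were tested on simulated data with independent noise for this comparison. Over 29541 simulated transcript clusters they recovered 71% of 100 changed by 0.5 log2 and 96% of 100 changed by 1 log2, with 8 false calls, and made 0 calls when none was changed. The simulation held no correlation between genes, so these rates need not hold for the real arrays, in limma or in camera.

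In the closing tests, bounds were written before each test was run, some of them after related values had been seen, and an explanation was set aside only where its bound was passed. For the erythroid, normalisation and innate lymphoid tests, the further demand that the bound be passed by more than 1 standard error was added after the values were seen. Without that demand, the erythroid and innate lymphoid explanations would have been set aside. It was not kept for knockout replicate 1, since leaving out an array removes all of its effect; that too was decided after the values were seen. The erythroid list without that array was held to the bounds of the cell cycle list, and this test was added after its values were seen. The bound for setting aside flanking sequence was moved from the 90th to the 50th percentile after the value was seen, which leaves that explanation open. A looser rule, tried after the values were seen, would have set aside all 3 explanations of the cell cycle pattern; it was not used.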

Results

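Transcript levels were measured in lineage-depleted bone marrow, the fraction of marrow left after magnetic removal of cells carrying NK1.1, CD2, B220, CD11b, GR1 or Ter119. This fraction is rich in stem and progenitor cells. Each of 12 arrays held the RNA of a separate mouse, 6 of them E4bp4 knockout and 6 wild type. E4bp4 is another name of Nfil3, a basic leucine zipper transcription factor needed for the development of natural killer (NK) cells. Median log2 levels of the arrays ran from 6.50 to 6.62. Correlations between arrays over all 34760 transcript clusters, before the filter, lay between 0.986 and 0.9955. Sample number, 6 per genotype, limits the precision of every value below.

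The targeted gene was compared first. Nfil3 was lower in the knockout by -0.68 ± 0.13 log2 (SE), a 1.61-fold difference, with means of 6.49 ± 0.23 (SD) in the knockout and 7.18 ± 0.25 in the wild type. The genotypes did not overlap: knockout replicate 2, at 6.92, was the highest knockout array and wild type replicate 5, at 6.94, the lowest wild type array. A two-sided exact permutation test of the 12 Nfil3 values gave p = 0.00216, the smallest that the 924 permutations can give. The adjusted p of the limma fit over all transcript clusters was 0.14 for Nfil3, so it did not pass that threshold. Which part of the gene was deleted is not given in the sources used here, so a remaining signal from probes outside the deletion cannot be separated from transcript left in the knockout.

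The series asks which genes E4bp4 regulates in bone marrow. Among named genes higher in the knockout, Cap2, a regulator of actin, had the lowest p-value. The 10 named genes of lowest p among those lower in the knockout included Trgv1, a variable segment of the T cell receptor gamma locus, and Icos, a costimulatory receptor of lymphocytes. Cap2 was at 8.26 in the knockout and 7.38 in the wild type, a difference of 0.88 ± 0.13 log2. It lies within 10 Mb of Nfil3, so an effect of E4bp4 on it was not separated from one of the targeted locus. Trgv1 was at 5.14 and 6.49, a difference of -1.34 ± 0.21 log2; its knockout arrays went down to 4.89, below the 20th percentile of that array (4.96), and a level this close to background can understate a difference. No transcript cluster of 29541 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.109. At an unadjusted p under 0.05 there were 4391 transcript clusters, where chance gives 1477 on average. Of these, 2502 were higher and 1889 lower in the knockout. The percentage higher under that p was 57 with the authors' values, 46.9 after quantile normalisation and 22 after centring each array on its median. With the authors' values and a 50th percentile filter it was 47.5. The balance of directions thus rested on the scaling and the filter. The arrays of both genotypes did not overlap for 375 transcript clusters, where chance gives 63.94.

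The 10 genes of lowest p in each direction did not pass the adjusted threshold and are given as values. Higher in the knockout, besides Cap2, were Pik3c2b, Cabp4, DQ267102, Pdlim7, Syce1l, Tpm4, Kcnk6, Pou2af1 and F5. Pou2af1, a B cell coactivator, differed by 0.68 ± 0.13 log2, and Tpm4, a tropomyosin, by 0.40 ± 0.073. F5, coagulation factor V, differed by 0.48 ± 0.092 log2 and Kcnk6, a potassium channel, by 0.47 ± 0.089. Lower, besides Trgv1, Icos and Nfil3, were Ginm1, Gpr141b, Tmem128, Slbp, Chaf1b, Hmgb1-rs17 and Pi4k2b. Slbp, the histone mRNA stem-loop binding protein, differed by -0.26 ± 0.044 log2 on the transcript cluster of lowest p and by -0.20 ± 0.068 on its brighter one (adjusted p 0.23). Chaf1b, a subunit of chromatin assembly factor 1, differed by -0.18 ± 0.031. Hmgb1-rs17 is a sequence related to Hmgb1, and its signal is uncertain for that reason. Leaving out knockout replicate 1 brought Cap2 to an adjusted p of 0.0287 in limma and Gpr141b to 0.044, while leaving out both arrays numbered 1, an alternative chosen after seeing the data, gave 0.105 for both; leaving out wild type replicate 2 brought Trgv1 to 0.0178.

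**Figure D1:**
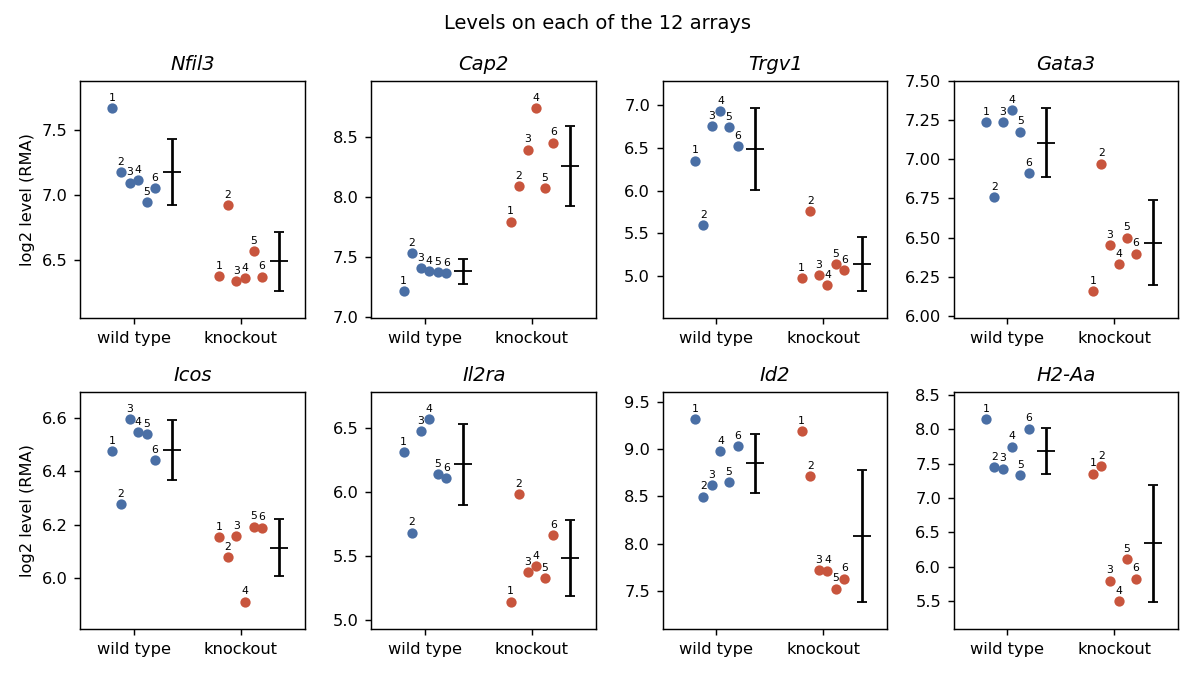
Log2 levels (RMA) of Nfil3, Cap2, Trgv1, Gata3, Icos, Il2ra, Id2 and H2-Aa on each array, wild type in blue and knockout in red, numbered by replicate, with the mean and SD of 6 arrays as black bars; vertical axes differ between genes and do not start at 0. The knockout arrays for Nfil3 lie between 6.34 and 6.92 and the wild type arrays between 6.94 and 7.67, while Id2 is at 9.19 and 8.72 on knockout replicates 1 and 2.

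Genes of NK and innate lymphoid development were compared because E4bp4 acts in those lineages. Gata3, a transcription factor of T cells and innate lymphoid cells, was lower by -0.64 ± 0.13 log2, at 6.47 in the knockout and 7.11 in the wild type. Id2, an inhibitor of E proteins, was at 8.08 ± 0.70 (SD) and 8.85 ± 0.31, a difference of -0.77 ± 0.28 (SE). Eomes, a T-box factor of mature NK cells, differed by 0.07 ± 0.050 log2, at 5.41 and 5.34. The exact permutation p was 0.00649 for Gata3, 0.0411 for Id2 and 0.177 for Eomes, and their limma adjusted p-values were 0.148, 0.255 and 0.517. Id2 was uneven among the knockout arrays: replicates 1 and 2 were at 9.19 and 8.72 and the other knockout arrays reached at most 7.72. Among the other genes chosen before the data were examined, differences were 0.03 for Tbx21, 0.01 for Tox, 0.09 for Ets1, 0.02 for Il2rb, -0.27 for Il7r and 0.18 for Zbtb16. They were 0.10 for Dbp, 0.01 for Per2, 0.10 for Bcl2l1 and 0.16 for Il3ra, and none passed the adjusted threshold. Tcf7 was not tested here.

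The list Innate lymphoid progenitors had 13 of 19 genes lower in the knockout, with a mean difference of -0.143 ± 0.060 log2 (SE) but a median of -0.024. The largest differences were those of Id2, Il2ra, Gata3 and Icos. Its shift passed camera, limma's competitive gene set test, at an adjusted p of 0.0114 with the preset correlation, and gave adjusted p = 0.559 with an estimated correlation; with a 50th percentile filter camera gave 0.143. Over all transcript clusters 0 of its members passed; adjusted over the list alone, 3 did, namely Icos (-0.37 ± 0.063), Gata3 and Il2ra, the alpha chain of the interleukin 2 receptor (-0.73 ± 0.16). The NK cell marker list did not pass, with 11 of 14 genes higher and a camera adjusted p of 0.723. Adjusted over the list alone, 1 NK marker passed, the chemokine Ccl5, at -0.23 ± 0.058 log2. Of 27 NK development regulators 19 were higher, with a camera adjusted p of 0.613, and Gata3 and Irf2 passed adjusted over the list alone, both lower in the knockout.

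In camera with the preset correlation, the cell cycle and erythroid lists shifted lower in the knockout and the megakaryocyte list higher; with an estimated correlation none of them did. Of 33 cell cycle genes 31 were lower, by -0.102 ± 0.026 log2 on average, among them the replication helicase subunit Mcm4 (-0.17 ± 0.036) and the mitotic spindle gene Nusap1 (-0.21 ± 0.056). Of 27 erythroid genes 26 were lower, by -0.145 ± 0.074 log2 on average, such as Fech, the last enzyme of haem synthesis (-0.22 ± 0.074). All 17 megakaryocyte and platelet genes were higher, by 0.379 ± 0.16 log2, including both chains of the platelet fibrinogen receptor, Itga2b (0.41 ± 0.11) and Itgb3 (0.62 ± 0.20). Camera adjusted p-values with the preset correlation were 2.91e-14 for cell cycle, 8.98e-08 for erythroid and 7.46e-07 for megakaryocyte genes. With an estimated correlation the adjusted p was 0.313 for cell cycle and 0.559 for erythroid and for megakaryocyte genes. Exact permutation tests of the list means gave p = 0.00649, 0.0693 and 0.0411, and 0.0758, 0.176 and 0.148 adjusted over the 28 lists. Adjusted over the list alone, 11 cell cycle genes passed, all lower, as did 5 megakaryocyte genes, all higher, and 0 erythroid genes; over all transcript clusters 0 passed in any of them. Without knockout replicate 1 the erythroid mean difference was -0.0955 (exact permutation p = 0.149) and the cell cycle one -0.0885 (exact permutation p = 0.013). The megakaryocyte mean difference was then 0.49. Knockout replicate 1 had the lowest megakaryocyte list mean of the knockout arrays, 9.14, and so widened the error of that list. Camera with an estimated correlation still passed 0 lists without it.

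The haematopoietic stem cell list was higher in the knockout, with 19 of 21 genes higher by a mean of 0.108 ± 0.021 log2 (SE). Tek, an angiopoietin receptor, differed by 0.19 ± 0.050, the adhesion molecule Esam by 0.28 ± 0.079, and Kit, the stem cell factor receptor, by 0.19 ± 0.064. Camera gave an adjusted p of 0.00192 with the preset correlation, and adjusted p = 0.247 with an estimated correlation. Adjusted over the list alone 5 passed, all higher: Tek, Esam, Mycn, Gata2 and Kit. Of these, Tek and Esam also stand in the endothelial list, and Gata2 and Kit in the basophil and mast cell list. Kit stands in the innate lymphoid progenitor list as well. Results of these lists are therefore not independent. The exact permutation test of the list mean gave p = 0.00216, or 0.0606 adjusted over the 28 lists.

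Lists of other marrow cells shifted in camera with the preset correlation, and each lost its call with an estimated one. Stromal and bone cell genes were lower, 21 of 25, by -0.153 ± 0.11 log2 (camera adjusted p 0.00109). They gave adjusted p = 0.559 with an estimated correlation and an exact permutation p of 0.203, and without wild type replicate 5 the difference was -0.0852 and the camera adjusted p 0.0407. Ribosomal protein genes were lower, 20 of 28, by -0.032 ± 0.011 (0.00461), with adjusted p = 0.559 with an estimated correlation and 0.499 after quantile normalisation; many have pseudogene copies, so these signals are uncertain. Plasma cell genes were higher, 13 of 16, by 0.186 ± 0.068 (0.00461), with adjusted p = 0.559 with an estimated correlation, and Pou2af1 passed adjusted over the list alone. Basophil and mast cell genes were higher, 20 of 21, by 0.166 ± 0.14 (0.0103), with adjusted p = 0.632 with an estimated correlation. Their camera adjusted p was 0.166 without knockout replicate 1 (mean difference 0.0874) and 0.111 without wild type replicate 5 (0.104). B cell precursor genes were higher, 19 of 23, by 0.128 ± 0.055 (0.0133), with adjusted p = 0.559 with an estimated correlation; Pou2af1 and Fcmr passed adjusted over the list alone. That call was also lost without knockout replicate 1 (0.113), knockout replicate 2 (0.0665) or wild type replicate 4 (0.0517).

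The conventional dendritic cell list, with 9 of 19 genes higher and 10 lower, did not shift as a whole. H2-Aa, H2-Ab1 and H2-Eb1, chains of MHC class II molecules, differed by -1.34 ± 0.34, -0.55 ± 0.16 and -0.43 ± 0.085 log2, and Flt3, a cytokine receptor of early progenitors, by 0.36 ± 0.11. Other class II genes of the list were at -0.50 ± 0.25 (Cd74), 0.11 ± 0.11 (H2-DMa) and 0.0066 ± 0.059 (Ciita, their transactivator), chosen after their values were seen. H2-Aa, H2-Ab1, H2-Eb1 and Flt3 passed adjusted over the list alone and 0 passed over all transcript clusters; the list Conventional dendritic cells gave a camera adjusted p of 0.196. Without knockout replicate 1 it gave 0.0169 with the preset correlation and 0.77 with an estimated one, the latter an alternative chosen after seeing the data. Camera with the preset correlation also gave 0.0449 without wild type replicate 3.

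Camera adjusted p-values of the remaining lists lay above the threshold. They were 0.171 for common lymphoid progenitors, 0.229 for T cells, 0.362 for plasmacytoid dendritic cells, 0.224 for monocytes and macrophages, 0.965 for neutrophil primary granules and 0.068 for neutrophil later granules. They were 0.973 for eosinophils, 0.276 for endothelial cells, 0.723 for osteoclasts, 0.268 for skeletal muscle and 0.562 for circadian clock and PAR bZIP genes. They were 0.798 for interferon response, 0.26 for immediate early and stress genes, 0.796 for interleukin 3, interleukin 5 and GM-CSF signalling, and 0.613 for apoptosis regulators. Neutrophil primary granule, eosinophil and interferon response lists had positive mean differences (0.0602, 0.0866 and 0.0116) while camera placed them on the lower side. Each sign turned with single arrays left out: without wild type replicate 5 the neutrophil primary granule mean was -0.0339 and the eosinophil mean -0.0715, and without wild type replicate 3 the interferon response mean was -0.033. Without knockout replicate 1 the means were -0.146, -0.114 and -0.00328. The neutrophil primary granule list then gave a camera adjusted p of 0.0477 with the preset correlation, but with an estimated correlation 0 lists passed without that array; over all arrays its exact permutation p was 0.842.

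**Figure D2:**
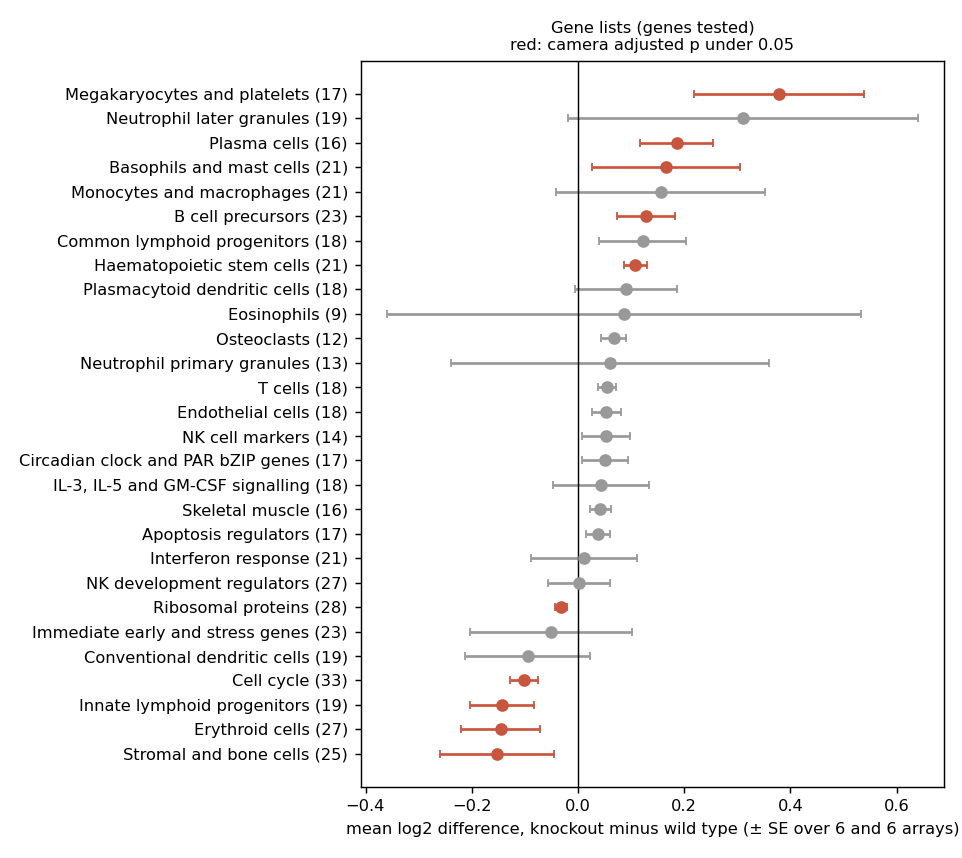
Mean log2 difference, knockout minus wild type, of each gene list (horizontal axis), with bars of 1 SE over 6 and 6 arrays and the number of genes tested in brackets; red points have a camera adjusted p under 0.05 with the preset correlation. The megakaryocyte and platelet list lies highest, at 0.379, and the stromal and bone cell list lowest, at -0.153; 0 of the 28 lists pass with an estimated correlation.

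Knockout replicate 1 stood apart from the other arrays in sex-linked and granulocyte genes. Its Xist level was 6.08, against 12.1 to 12.65 on the others, and its Y-linked Eif2s3y and Uty were at 7.37 and 7.70, against at most 4.13 and 4.66. The neutrophil granule genes Ngp and S100a8 were at 12.01 and 10.57 there, against at most 10.21 and 8.91 elsewhere; these and Igha, at 12.7 against at most 9.34, were chosen after their values were seen. Its first principal component score was -44.4, the lowest of all arrays, and that component, 26.8% of the variance, was not related to genotype (exact permutation p = 0.552). The second component, 14.4% of the variance, separated the genotypes (exact permutation p = 0.00216).

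**Figure D3:**
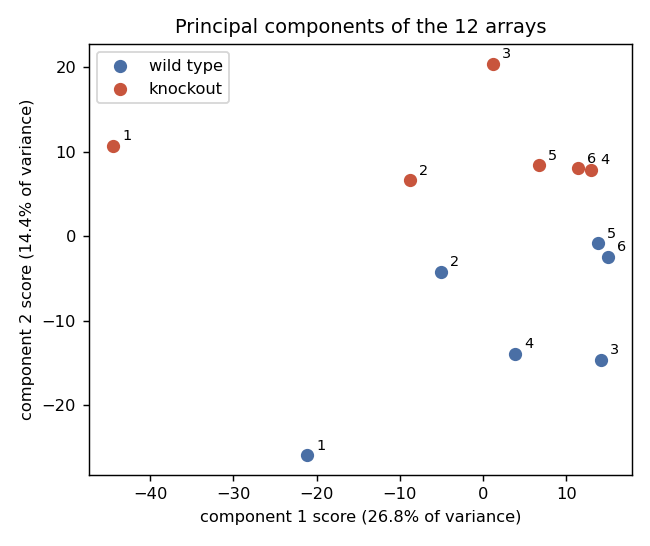
Scores of the 12 arrays on the first principal component (horizontal, 26.8% of the variance) and the second (vertical, 14.4%), wild type in blue and knockout in red, numbered by replicate. All knockout arrays lie above all wild type arrays on the second component, and knockout replicate 1 lies at -44.4 on the first.

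Genes near Nfil3 on its chromosome were compared with all others, since a targeted allele can carry flanking sequence of another strain. Within 10 Mb, Cap2 and Pdlim7 were higher in the knockout, at 0.88 ± 0.13 and 0.20 ± 0.037 log2, and Nol7 was lower, at -0.24 ± 0.056; Nol7 was chosen after its value was seen. These were the 3 of 157 genes with an unadjusted p under 0.001 (1.91%), against 0.612% of genes elsewhere, and a two-sided Fisher's exact test gave p = 0.075. Leaving out 1 array at a time gave 2 to 4 such genes near Nfil3 with an unadjusted p under 0.001 and Fisher's exact p from 0.00597 (without knockout replicate 2) to 0.276 (without knockout replicate 6), so the result depended on single arrays. Within 5 Mb it was 1 of 95 genes (1.05%) against 0.621%, with Fisher's exact p = 0.449, and within 20 Mb 5 of 263 (1.9%) against 0.604%, with p = 0.0245. At an unadjusted p under 0.05 the percentages were 18.5 within 10 Mb against 15.2 elsewhere (Fisher's exact p = 0.263) and 17.1 within 20 Mb against 15.2 (p = 0.386). At the adjusted threshold 0 of the 157 genes passed.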

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

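The tests of sex and of a shared batch for knockout replicate 1, that of the erythroid list without it, and the tests of flanking sequence and of strain variants near Nfil3, were chosen only after the result was seen. A sample was picked out here when its gap to the nearest array of its genotype exceeded 0.625 of the genotype's range. Of 320 sets of 6 values 27 met this, where chance gives about 16, and 13 of them were in knockout replicate 1.

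In knockout replicate 1, sex-linked genes lay far from the other knockout arrays, with Xist at 6.08, Eif2s3y at 7.37, Kdm5d at 6.98 and Uty at 7.70. Myeloid genes were also apart, with Ccr3 at 6.95, Cd177 at 7.80, Itgb2l at 6.89, Mmp8 at 6.59 and Mrc1 at 7.11. Flt3 was at 10.01 and DQ267102 at 6.54. The monocyte and macrophage list mean was 8.42 and the megakaryocyte and platelet list mean 9.14.

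Single values stood apart on other arrays. In the knockout these were Trgv1 at 5.76 in replicate 2, Rpl5 at 12.26 in replicate 3, Eomes at 5.59 and Fcrla at 6.03 in replicate 5, and Tnfrsf10b at 5.98 in replicate 6. In wild type replicate 1 they were Cd79a at 5.39, Flt4 at 6.00, Nfil3 at 7.67 (7.665) and the NK development regulator list mean at 8.20. In wild type replicate 2 they were Ccr9 at 6.08 and Itga2b at 9.07 (9.065). Marco was at 6.15 in wild type replicate 3, and Nr1d1 at 8.16 (8.155) and the erythroid list mean at 11.51 in wild type replicate 6.

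Knockout replicate 1 had the highest or lowest mean of all 12 arrays in 20 of 28 gene lists, so another mixture of cells, with more granulocyte and monocyte RNA than the depletion of CD11b and GR1 cells should leave, may account for it. The bound was 10 lists, which knockout replicate 4 also reached, with 10, and the lists share genes. In knockout replicate 1 the neutrophil later granule list averaged 8.58 against at most 7.33 elsewhere, with Ngp at 12.01 and Lcn2 at 11.09. The autosomal deviations of knockout replicate 1 correlated at 0.667 with those of wild type replicate 1, which carries female signal, the highest of 36 pairs (next 0.5). This argues against sex alone for the pattern that these arrays share. A correlation ignores size, and wild type replicate 1 was only at 7.14 for the neutrophil later granule list. The test therefore cannot speak on departures that wild type replicate 1 did not share. That correlation, 0.667 over 17195 autosomal genes, which are not independent replicates (0.46 over all tested transcript clusters), is also what a batch shared by the arrays numbered 1 would give. Labels name neither sex nor batch, so a shared batch and a shared cell mixture both stay open for the shared pattern. For departures that wild type replicate 1 did not share, sex stays open too.

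Low p-values near Nfil3 may reflect flanking sequence or a local effect of the targeted allele: the mean absolute moderated statistic within 10 Mb, 1.35, lay at the 87.4 percentile of 1993 windows on other chromosomes (median 1.24). That value is above the median and short of the 95th percentile written as the bound, so it leaves flanking sequence open. Strain variants that only weaken probe binding are argued against for Cap2 and Pdlim7, the 2 of 5 genes under p 0.001 within 20 Mb that were higher in the knockout. They stay open for the 3 lower genes, Pak1ip1, Prxl2c and Nol7, named after their values were seen. An effect of E4bp4 itself on these genes was not tested apart from the targeting.

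Lower cell cycle and erythroid lists may come from fewer erythroid precursors or from the authors' normalisation, while knockout replicate 1 as the whole cause is argued against for the cell cycle list only. Without that array 0.865 of the cell cycle difference was left (-0.0885 ± 0.0241 SE, exact permutation p = 0.013), but 0.658 of the erythroid one (-0.145 ± 0.0744 before, -0.0955 ± 0.0615 after, exact permutation p = 0.149), short of the bound of 0.8, so knockout replicate 1 stays open for the erythroid list. With the erythroid list mean as a covariate, 0.538 of the cell cycle difference was left (-0.055 ± 0.0129 SE), over the bound of 0.5 by less than 1 SE, and a list mean corrects for a cell type imperfectly. After quantile normalisation 0.762 was left (-0.0779 ± 0.0248, exact permutation p = 0.00866), short of the bound of 0.8. A genotype effect on proliferation stays open beside both.

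Of the 462 ways to split the 12 arrays into 6 and 6, 100 were run, the real one included. For transcript clusters past the adjusted threshold the real value was 0, so all 100 had to give as many and the splits test nothing; the highest other was 1. For an unadjusted p under 0.05, only 1 of 100, the real one, reached 4391, the highest other being 4083. That makes chance unlikely but does not exclude it, which running all 462 splits could not do either. For gene lists past camera's threshold, chance cannot be excluded, since 34 of 100 gave at least the real 10 and the highest other gave 19.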

How the results depend on the processing

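Leaving out both arrays numbered 1, the exact permutation of list means and the estimated correlation without knockout replicate 1 were chosen after seeing the data. Nfil3 was lower in every setting run, between -0.77 and -0.56 log2. Transcript clusters past the adjusted threshold numbered 0 in limma, 5 with array weights, 3 with a sex-linked covariate and 0 to 4 over the arrays left out: 4 without knockout replicate 1, 1 without knockout replicate 2 and 1 without wild type replicate 2. Cap2, Gpr141b and the unnamed transcript cluster 10409276 passed with array weights, with the covariate and without knockout replicate 1. In limma 10409276 also passed without knockout replicate 2 (adjusted p 0.00837). Without both arrays numbered 1, 0 passed (smallest 0.105), with fewer arrays. Cap2 lies within 10 Mb of Nfil3, and the identifier of 10409276 lies between those of Auh and Nfil3. For these 2 an effect of E4bp4 was not separated from one of the targeted locus. The sex-linked covariate rests on knockout replicate 1, the only array with male signal. Of changed genes near Nfil3 on its chromosome, 1, Cap2, passed with array weights (Fisher's exact p = 0.0262) and with the sex-linked covariate (0.0176), and 0 to 1 over the arrays left out (0.0176 without knockout replicate 1). Gene lists past the threshold numbered 10 with camera, 0 with an estimated correlation, 2 with fry (cell cycle and stem cells), 0 by exact permutation and 0 with an estimated correlation without knockout replicate 1. The cause of these moves was not tested. By exact permutation 1 list alone could not pass, since the smallest possible p, 0.00216, becomes 0.0606 over the 28 lists. Counts at an unadjusted p under 0.05 stayed between 3116 and 5149. With the replicate number as a block, 0 transcript clusters, 5149 unadjusted and 11 lists passed. Genes near Nfil3 with an unadjusted p under 0.001 then gave Fisher's exact p = 0.0491. Over all tested transcript clusters, deviations of same-numbered arrays from their genotype means correlated from -0.033 to 0.46 (the arrays numbered 1). These correlations were over 0.1 in 3 of 6 pairs, and 4 of 12 arrays matched their own number best. These values were not tested against chance. They do not show that the numbers pair the samples as a set, but partial pairing by number stays open, as does a batch of the arrays numbered 1. Among named genes (Slbp by its brighter transcript cluster) 2614 comparisons kept their side of the threshold and 8 passed it anew; among lists 659 kept it, 48 lost the call and 21 gained it. No gene changed the sign of its difference with a call, and no list changed camera's direction with one. The mean difference of the neutrophil primary granule list did change sign, from 0.0602 to -0.146 without knockout replicate 1, where camera called it. Lists that passed only in some settings include neutrophil later granules and immediate early genes (0.00533 without knockout replicate 1), all with the preset correlation. Signal near background limits Trgv1, Il2ra and Eomes.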

Other observations

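The test of a separate marker list for group 2 innate lymphoid cells was chosen only after the result was seen, and some of its genes had been looked at before. The transcript cluster with the lowest p, 10409276, has no gene in the annotation used here. It was at 6.69 ± 0.39 (SD) in the knockout and 5.57 ± 0.07 in the wild type, a difference of 1.12 ± 0.15 log2 (SE), with a limma adjusted p of 0.109, and 0.00837 without knockout replicate 2. Its identifier lies between those of transcript clusters named Auh and Nfil3. It was chosen after its values were seen, and its position was not analysed here.

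Lower Gata3, Icos, Il2ra and Id2 may reflect fewer group 2 innate lymphoid cells or their precursors, as a hypothesis. A list of 14 further markers of these cells, 9 of them tested, differed by -0.0146 ± 0.0627 log2 (SE), at 7.21 in the knockout and 7.23 in the wild type (exact permutation p = 0.82). Without knockout replicate 1 the difference was -0.0535 (exact permutation p = 0.344). Of these 9 genes 5 were lower, and Crlf2 and Samsn1, at 8.49 and 9.44 in the knockout, were among the highest. Of those tested, Rora, Il17rb, Il4 and Il13 also stand in the earlier lists. The error is wider than the bound of -0.05, so these arrays cannot decide for or against the hypothesis.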
